A study of Arabidopsis thaliana with 9 samples.

How the data were processed

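RNA-seq libraries were made from dark-grown Arabidopsis thaliana seedlings aged 3 days. Per the labels, 3 genotypes were collected with 3 replicates each: the wild type Col-0, the mutant cop1-4 and the mutant spaQ, the mutants in the Col-0 background. Per the labels' protocols, seeds were stratified for 3 days at 4 °C in the dark, given 3 h of white light and 21 h of darkness, treated with far-red light and kept in the dark for 2 more days. Total RNA was extracted with a Sigma spectrum kit and libraries followed Illumina TruSeq procedures, per the labels' protocols. Nothing in the labels says whether replicates came from separate sowings, so p-values measure the spread between these libraries, which may be technical. Library batches and dates are not given in the sources used here.

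The authors deposited a table of raw read counts per gene, with a column for each of the 9 libraries. The submitters' processing notes name FastQC, Bowtie2, TopHat, HTSeq and DESeq2 and the genome build TAIR10, without versions. The strand setting of the counting is not stated, so reads of overlapping and antisense genes cannot be told apart, and such genes are named as uncertain. The authors also deposited a table of regulated genes for each mutant against the wild type, with log2 fold changes and adjusted p-values. Those values were used only for comparison with the calls made here. The processing notes do not state whether DESeq2 made the authors' deposited tables.

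The count table held 33655 features, of which 32548 had gene identifiers starting with AT and 1107 had identifiers starting with ENSRNA. No feature was organelle-encoded, 0 features named no gene, and 7726 features were at 0 in every library. A TAIR10 gene table matched all 32548 AT identifiers and was used for names, overlap between genes and which genes neighbour each other. Of 746 protein-coding genes overlapped over at least 90% of their length by another gene, 443 (59.4%) were at 0 in every library, against 2940 of 23905 (12.3%) overlapped over less than 10%. Such a 0 does not show that a gene was silent. List members with at most 27 reads over all libraries, which were not tested, were MYC2, LHCB1.5 and GGPS1, each overlapped over most of its length, and MYB29, MYB76, CYP79F1, BAM5, MAH1, PR2, CYP71A13, PDF1.2, LOX2, TAT3, LEC1 and LEC2.

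Counts were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) after filterByExpr and TMM scaling. A fit over all 9 libraries with genotype as the term had 6 residual degrees of freedom and a common dispersion of 0.008649. It covered 20779 genes and gave 3 comparisons: cop1-4 against Col-0, spaQ against Col-0 and spaQ against cop1-4. A gene was called at a Benjamini-Hochberg adjusted p-value below 0.05 over all genes tested. Counts of genes called at 2-fold also required an absolute log2 fold change of at least 1. The standard error (SE) of a log2 fold change was taken from the fold change and its test statistic. Levels are CPM values (the count of a gene scaled to a common library size, with TMM-adjusted totals), as mean ± SD with n = 3 libraries. Where every library of a group was at 0, the fold was computed against a floor of 3 counts per library and is a lower bound. Intervals and floors of this kind cover counting error only.

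A set of 28 gene lists with 435 entries (433 different genes) was fixed before the data were examined, as were the groups, the test, the settings to be varied and the rule for named genes. The lists covered the targeted loci, light-harvesting antenna, photosystem subunits, Calvin cycle, chlorophyll biosynthesis, carotenoid biosynthesis, flavonoid and anthocyanin biosynthesis, light-signalling regulators, PIF factors and their dark- or shade-induced targets, auxin response, brassinosteroids, gibberellins, ethylene, expansins and xyloglucan enzymes, the circadian clock, photoprotection and UV response, glucosinolates, fatty acid breakdown and the glyoxylate cycle, starch, nitrogen assimilation and photorespiration, cuticular wax, salicylate and pathogen defence, jasmonate, stomatal lineage and guard cells, root markers, cell division, seed storage and late embryogenesis, and reference genes. Each list was set against the other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 28 lists. The test was repeated with an estimated correlation between genes, and fry was run as a test of movement in either direction on balance.

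By the rule for named genes, each comparison names the targeted loci, the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 1 whose libraries did not overlap between the genotypes, and up to 4 members of each list with the lowest adjusted p-values. Other list members could be named with their values.

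The pipeline was tested on simulated data for the real libraries, with 200 genes changed. All 200 were drawn from genes above 1 CPM in Col-0, so the recovered shares do not cover genes with lower counts there. Rises and falls were equal in number and the same in both mutants. The simulation therefore does not cover scaling where most genes change, as they did in the real comparisons with Col-0 (62.1% and 71.6% of genes called). For cop1-4 against Col-0 it recovered 70% of genes changed 1.5-fold, 92% of those changed 2-fold, 98% at 4-fold and 100% at 8-fold, with 9 of 20164 unchanged genes called. For spaQ against Col-0 it recovered 72% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 18 of 20164 unchanged genes called. For spaQ against cop1-4, where the simulation held no change, 0 of 20364 genes were called. None of 28 unchanged lists was called by camera and 1 by fry. Genes were drawn independently of each other there, whereas estimated correlations within the real lists reached 0.808. The simulation therefore does not test camera on lists whose members move together.

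Alternatives tried were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, fits on the compared genotypes alone, each library left out in turn, libraries thinned to the smallest total and a threshold of 0.01. Scaling by library totals and leaving out 6065 genes that overlap another gene were added after the data had been seen.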

Results

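Transcript counts were compared between 3-day-old dark-grown Arabidopsis seedlings of the wild type Col-0 and of the mutants cop1-4 and spaQ, with 3 libraries for each genotype. COP1 is the RING-type ubiquitin ligase that, together with SPA proteins, holds back light responses in darkness. The name cop1-4 stands for a weak COP1 allele, and spaQ is the usual name of a mutant in SPA1, SPA2, SPA3 and SPA4. The design asks which transcripts of etiolated seedlings depend on COP1 and which on SPA proteins, and the series title places the emphasis on developmental and metabolic pathways.

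The 9 libraries held from 22482588 (cop1-4 replicate 3) to 38770474 (spaQ replicate 2) counted reads. Col-0 totals were 32300852, 27651857 and 28247653, and the remaining totals were 33395264 and 27053939 for cop1-4 and 30019301 and 28523301 for spaQ. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 3.27 to 20.4 between pairs, so no library was a second copy of another. In Col-0 the most abundant transcripts came from the aquaporin gene TIP2 (0.912% of counts), the beta-glucosidase gene PYK10 (0.839%) and the catalase gene CAT3 (0.676%). In cop1-4 and spaQ the leading transcripts came from the photosynthesis genes RBCS1A (1.45% and 1.80%) and RCA (1.09% and 1.2%), and the 10 most abundant genes took 6.6% to 6.81% of counts against 4.36% to 4.71% in Col-0. TMM scaling placed the median of all genes near 0 (0.01, -0.02 and -0.01 in the 3 comparisons), whereas library totals alone moved it to -0.31, -0.39 and -0.07. Changes are therefore given relative to the median gene.

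The targeted loci were examined in each genotype before any other gene. COP1 transcripts stood at 31.5 ± 3.00 CPM in Col-0 and 31.5 ± 3.61 CPM in cop1-4 (SD, n = 3), a log2 fold change of 0.01 (SE 0.10, adjusted p = 0.949, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In cop1-4, SPA1 rose by 2.47 on the log2 scale, SPA3 by 2.19 and SPA4 by 1.67, and SPA2 rose by 0.30, a call that was lost without Col-0 replicate 1 (0.26), Col-0 replicate 3 (0.27) or cop1-4 replicate 1 (0.16). In the libraries labelled spaQ, no SPA locus was lower than in Col-0 with TMM scaling. SPA4 rose from 11.6 ± 1.26 to 61.8 ± 2.48 CPM and COP1 from 31.5 ± 3.00 to 79.2 ± 4.06 CPM (SD, n = 3), while SPA1 and SPA3 were higher by 0.32 and 0.37 and SPA2 by 0.06 (adjusted p = 0.610). Scaling by library totals turned the sign of the COP1 and SPA2 values in cop1-4 (-0.31 and -0.01) and, in spaQ, of the values of SPA1 (-0.05), SPA2 (-0.31) and SPA3 (-0.01). COP1 in cop1-4 and SPA2 in spaQ were then called lower. The labels do not give the spaQ alleles, and an insertion or point mutation can leave a counted transcript, so these counts do not check the spaQ label. The name spaQ below means the libraries labelled spaQ, and each direction drawn from them rests on that label.

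**Figure D1:**
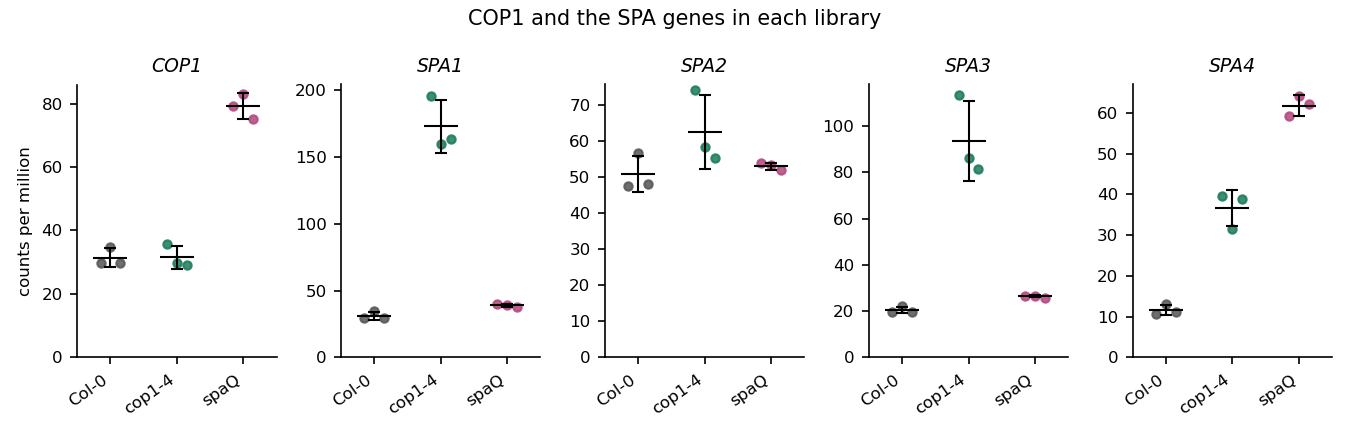
CPM (y axis) of COP1 and SPA1 to SPA4 in each library (points) of Col-0, cop1-4 and the libraries labelled spaQ, with the mean and SD of 3 libraries as bars. SPA1 reached 173 CPM in cop1-4 against 31.2 in Col-0 and 38.9 in spaQ, and SPA4 was highest in spaQ.

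Dark-grown cop1-4 seedlings had transcripts of most listed nuclear photosynthesis genes at levels far above the wild type. Organelle-encoded genes and proteins were not measured. All 17 measured light-harvesting antenna genes and all 22 photosystem subunit genes rose, and RCA, which encodes Rubisco activase, went from 445 ± 34.0 to 11610 ± 1199 CPM (SD, n = 3). Transcripts of growth hormone pathways moved the other way: 23 of 24 auxin response genes fell, among them IAA19, which went from 158 ± 14.7 to 7.47 ± 0.683 CPM. The auxin list includes SAUR19 to SAUR24, near-identical genes whose reads can be shared, so its counts of genes are uncertain in each comparison. PORA, whose product reduces protochlorophyllide and is typical of etiolated tissue, fell from 813 ± 38.8 to 20.4 ± 2.82 CPM, and 17 of 18 seed storage and late embryogenesis genes fell.

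The plastid lists moved together in cop1-4. The antenna list had a median log2 fold change of 3.25 (camera, adjusted p = 5.06e-12, and adjusted p = 0.17 with an estimated correlation). Its rises included LHCB1.1 (7.46) and LHCB2.1 (5.92), whose reads can be shared with near-identical family members, and LHCA1 of photosystem I (4.86). The photosystem list had a median of 2.81 (adjusted p = 6.51e-14, and adjusted p = 0.17 with an estimated correlation), with PSBO2 of the oxygen-evolving complex at 4.26 and PSAN at 4.12. Of 17 Calvin cycle genes 16 rose (median 3.14, adjusted p = 4.10e-10, and adjusted p = 0.17 with an estimated correlation), including RCA (4.71), the glyceraldehyde-3-phosphate dehydrogenase genes GAPB (4.3) and GAPA2 (4.11) and the aldolase gene FBA1 (3.96). The exception was RBCS2B, a near-identical small subunit gene, at -1.15. Chlorophyll biosynthesis had 21 genes higher and 2 lower (median 1.44, adjusted p = 2.36e-07, and adjusted p = 0.212 with an estimated correlation). CHLH, a subunit of magnesium chelatase, rose by 2.89 and HEMA1, which opens the tetrapyrrole pathway, by 2.15, and the 2 that fell were PORA (-5.32) and PORB (-3.21). All 12 carotenoid and plastid isoprenoid genes rose (median 1.42, adjusted p = 5.92e-07, and adjusted p = 0.17 with an estimated correlation), with the zeaxanthin epoxidase gene ZEP at 3.5 and the hydroxylase gene BCH2 at 2.51. Nitrogen assimilation and photorespiration had 11 genes higher and 1 lower (median 2.78, adjusted p = 5.57e-06, and adjusted p = 0.17 with an estimated correlation). The peroxisomal photorespiration genes HPR1 (4.19) and AGT1 (4.09) and the nitrate reductase gene NIA2 (2.63) rose, and the nitrate transporter gene NRT1.1 fell by 1.77. All 12 starch genes rose (median 1.87, adjusted p = 2.90e-06, and adjusted p = 0.212 with an estimated correlation), led by the beta-amylase gene BAM3 (4.70).

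Light-signalling genes were mixed in cop1-4. The list of regulators had 11 genes higher, 7 lower and 4 not called (median 0.27, or -0.05 with library totals, adjusted p = 0.221). BBX25, a B-box cofactor, rose by 5.89, the bZIP gene HYH by 2.98 and the chloroplast regulator GLK2 by 2.26, whereas HY5, the bZIP factor that promotes light responses and is a substrate of COP1, fell by 0.38 (SE 0.09), and FHL and FHY1, which carry phytochrome A into the nucleus, fell by 2.25 and 1.16. Of 17 PIF factors and dark- or shade-induced targets 12 fell and 5 rose (median -1.59, adjusted p = 0.00852, and adjusted p = 0.137 with an estimated correlation; 0.119 with library totals). PIF3 fell by 1.59, the shade marker PIL1 by 2.27 and the homeobox gene ATHB2 by 1.49, while the factors PIF7 (4.17), PIF5 (3.09) and PIF4 (1.60) rose. Photoprotection and UV response had 8 of 8 genes higher (median 2.74, adjusted p = 1.98e-05, and adjusted p = 0.137 with an estimated correlation), including RUP2 (3.90), a repressor of the UV-B receptor, the early light-induced genes ELIP2 (2.91) and ELIP1 (2.32) and the photolyase gene UVR3 (2.77). Of 16 clock genes 13 rose and 2 fell (median 1.51, adjusted p = 5.17e-05, and adjusted p = 0.137 with an estimated correlation), with PRR9 at 4.59, PRR5 at 4.47, PRR7 at 4.07, LNK2 at 3.39 and CCA1 at 2.58. Flavonoid and anthocyanin biosynthesis had 14 genes higher, 6 lower and 5 not called (median 1.19). Its adjusted p was 0.0612, and the list was called with no filter on low counts (0.0327), with library totals (0.00512) and without Col-0 replicate 1 (0.049), cop1-4 replicate 1 (0.0419) or cop1-4 replicate 2 (0.0407). UGT78D2, a flavonoid glucosyltransferase gene, rose by 2.67, CHI by 2.00, FLS1 by 1.76 and CHS, which encodes chalcone synthase, by 1.19, whereas PAL1 fell by 1.37 and the flavonol regulator MYB111 by 1.99.

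Hormone and cell wall lists were lower in cop1-4. Auxin response had a median of -2.12 (adjusted p = 1.07e-09, and adjusted p = 0.157 with an estimated correlation), with IAA6 at -6.47, IAA19 at -4.41 and IAA29 at -3.63, and IAA14 (0.27, or -0.05 with library totals) was the 1 member that rose. Of 12 ethylene genes 10 fell and 0 rose (median -1.4, adjusted p = 0.000274, and adjusted p = 0.137 with an estimated correlation), including ACS5 (-4.22), an ACC synthase gene, and HLS1 (-3.00), required for the apical hook. Gibberellin genes were lower in 10 cases and higher in 2 (median -0.89, adjusted p = 0.000791, and adjusted p = 0.137 with an estimated correlation), with the biosynthesis gene GA20OX1 at -5.13 and the DELLA gene RGL1 at -2.33. Brassinosteroid genes were lower in 10 cases and higher in 1 (median -0.64, adjusted p = 0.00171, and adjusted p = 0.137 with an estimated correlation), with BR6OX1 at -2.02 and DWF4 at -0.86, and the biosynthesis gene CPD was the 1 that rose (0.58). Of 23 expansin and xyloglucan enzyme genes 14 fell and 3 rose (median -0.90, adjusted p = 0.000679, and adjusted p = 0.317 with an estimated correlation). XTH17 fell by 4.84, XTH30 by 2.12 and EXPA11 by 1.94, and XTH22, known as touch-induced TCH4, rose by 2.65.

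Among the remaining lists in cop1-4, 13 of 14 stomatal lineage and guard cell markers rose (median 1.19, adjusted p = 0.000611, and adjusted p = 0.137 with an estimated correlation). They included BASL (2.39), SDD1 (2.19), SPCH (1.93), which starts the lineage, and TMM (1.91), and the guard cell channel gene KAT1 fell by 1.63. Seed storage and late embryogenesis had a median of -3.15 (adjusted p = 6.38e-06, and adjusted p = 0.256 with an estimated correlation), with the cruciferin genes CRU3 at -3.92, CRU2 at -3.90 and CRU1 at -3.81, and PAP85 (0.73) was the 1 that rose. Cuticular wax had 5 genes lower and 2 higher (median -0.98, also with WSD1 at its bound, adjusted p = 0.0321, 0.0949 with library totals, and adjusted p = 0.230 with an estimated correlation). CER1, needed for wax alkanes, fell by 2.75 and KCS1 by 2.55, and WSD1, a wax ester synthase gene at 6.40 ± 0.330 CPM in Col-0 (SD, n = 3), was at 0 in all cop1-4 libraries and so at least 54.3-fold lower. Jasmonate genes were lower in 6 cases and higher in 1 (median -0.99, adjusted p = 0.0421, and adjusted p = 0.230 with an estimated correlation), with VSP1 at -2.23, JAZ1 at -2.07 and the allene oxide cyclase gene AOC2 at 5.23. That call was lost with no filter (0.104), library totals (0.151) or without cop1-4 replicate 1 (0.062). Cell division genes were lower in 6 cases and higher in 1 (median -0.65, adjusted p = 0.0428, and adjusted p = 0.317 with an estimated correlation), with PCNA2 at -1.2 and CYCD3;1 at 1.02, and the call was lost with library totals (0.0773), the replicate block (0.0521) or without cop1-4 replicate 3 (0.0907). Salicylate and pathogen defence had 7 genes lower and 1 higher, among them PR1 at -3.23 (median -1.0). Its adjusted p of 0.0565 passed the threshold without Col-0 replicate 1 (0.049), cop1-4 replicate 2 (0.0431), cop1-4 replicate 3 (0.0478), spaQ replicate 2 (0.0304) or spaQ replicate 3 (0.0435). The targeted loci, as a list, had a median of 1.67 (adjusted p = 0.0227, and adjusted p = 0.317 with an estimated correlation). The lists that were not called were glucosinolates (9 higher, 7 lower, median 0.05, or -0.27 with library totals, adjusted p = 0.4), fatty acid breakdown and the glyoxylate cycle (7 higher, 4 lower, median 0.19, or -0.13 with library totals, adjusted p = 0.442), root markers (8 higher, 3 lower, median 0.61, adjusted p = 0.313) and reference genes (3 higher, 1 lower, median 0.07, or -0.245 with library totals, adjusted p = 0.4). Among their members UGT74C1, an aliphatic glucosinolate gene, rose by 4.15 and MYB51, a regulator of indole glucosinolates, fell by 1.48. The peroxisomal malate dehydrogenase gene PMDH2 rose by 3.21 and the isocitrate lyase gene ICL by 1.33, and the endodermis gene CASP1 fell by 1.53. Counts adjusted over the list alone were the same except for 8 lower glucosinolate genes, 5 lower fatty acid genes and 9 higher root markers.

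The largest rises in cop1-4 under the rule for named genes, which leaves out genes with low counts, were those of the cytochrome P450 gene CYP706A6, at 0 in all Col-0 libraries and at 10.2 ± 0.669 CPM in cop1-4 (SD, n = 3), at least 117-fold higher, the protein kinase gene CIPK20 (9.18), the thionin gene THI2.2 (8.71), the aldolase gene FBA5 (8.55), AT3G28270 (8.50), AT2G15020 (8.41), AT5G62240 (8.30), AT1G65490 (8.24), the alternative NAD(P)H dehydrogenase gene NDA1 (7.87) and the resistance gene RPP4 (7.85), which has close relatives in a cluster. Without Col-0 replicate 1 the values of AT5G62240 and AT1G65490 were 9.00 and 8.99. The largest falls under that rule were those of the peroxidase gene AT1G49570 (-8.39), AT3G43850 (-7.38, or -6.70 without cop1-4 replicate 1 and -11.46 without replicate 3), the marneral synthase gene MRN1 (-7.10), AT4G35720 (-6.01), the berberine bridge enzyme-like gene AT5G44440 (-5.41), PORA, AT1G20790 (-5.31), the pectin methylesterase gene ATPMEPCRD (-5.30), AT3G18530 (-5.28) and AT5G22500 (-5.18), the last pair overlapping other genes in part.

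In total, 12909 of 20779 genes (62.1%) were called between cop1-4 and Col-0 by edgeR's quasi-likelihood test, 6612 higher and 6297 lower, and 5124 of them changed at least 2-fold (2699 higher, 2425 lower). The 2 groups of libraries did not overlap for 65.7% of genes, where chance gives 10%. With library totals 28.5% of 14307 called genes were higher, against 51.2% with TMM. Of the 28 lists 21 were called, 11 upward and 10 downward, and none was called with an estimated correlation, where the lowest adjusted p was 0.137.

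**Figure D2:**
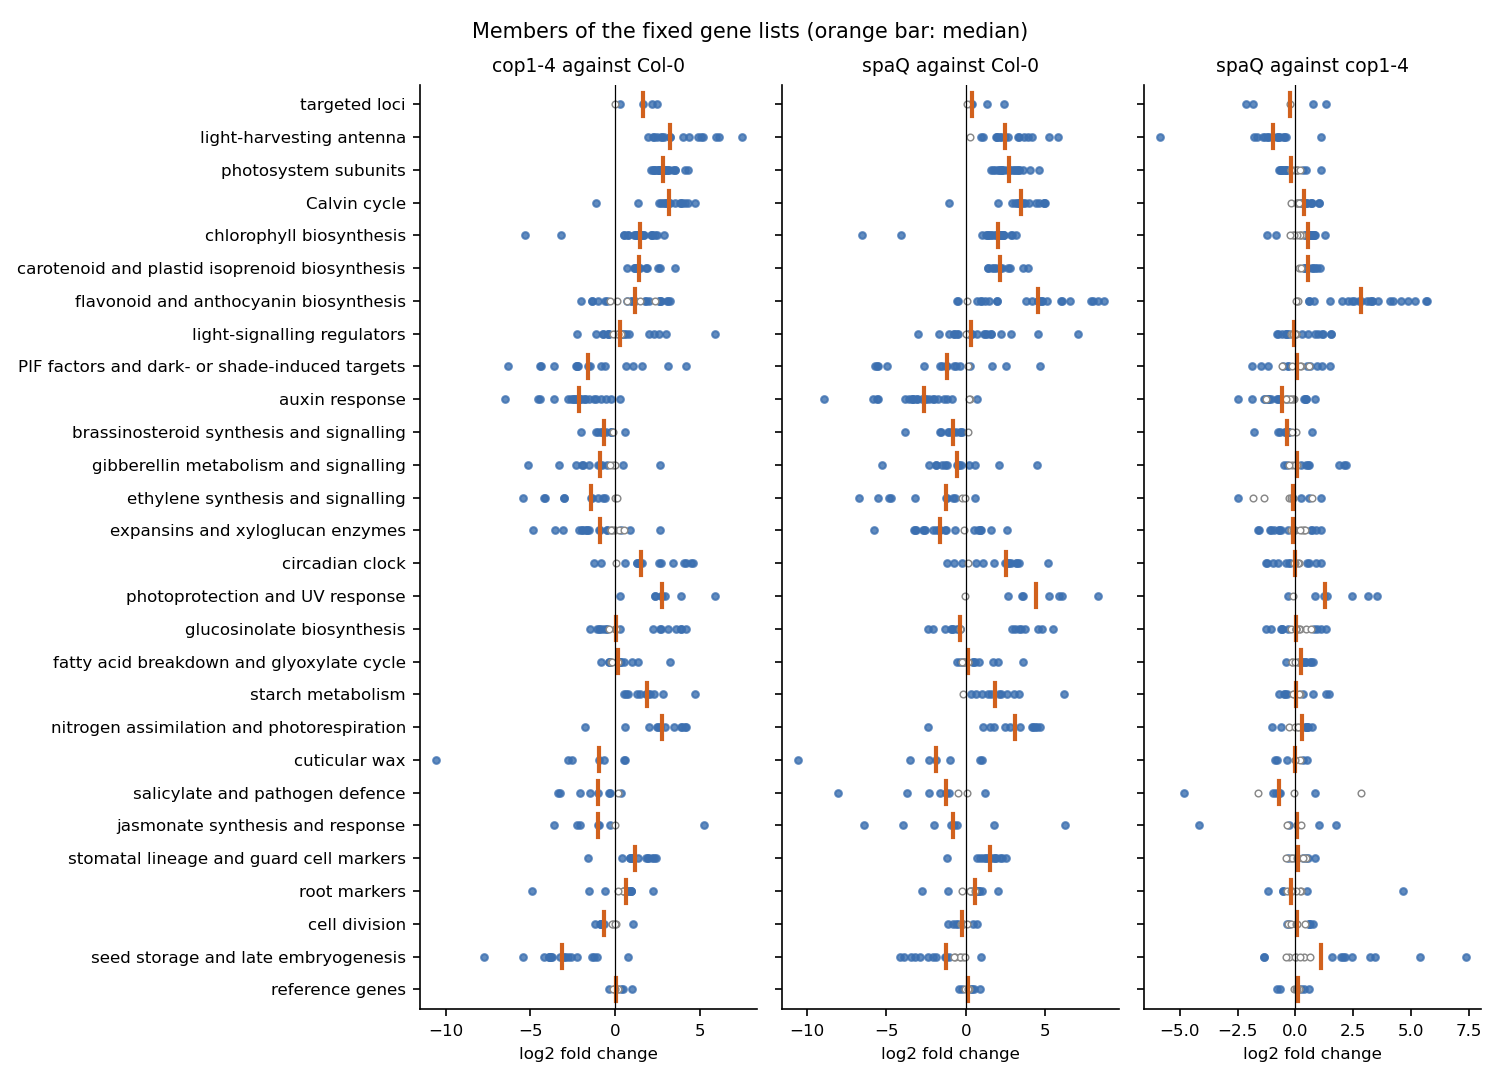
log2 fold changes (x axis) of the members of the 28 gene lists (y axis) in the 3 comparisons, with filled points for called genes, open points for genes not called and an orange bar at the median. The antenna list has its median at 3.25 in cop1-4 and 2.43 in spaQ, and the flavonoid list at 1.19 and 4.55.

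In the libraries labelled spaQ, the plastid gene groups stood above Col-0 as in cop1-4 and the flavonoid pathway stood higher still. CHS went from 22.3 ± 3.27 CPM in Col-0 to 613 ± 87.4 CPM in spaQ (SD, n = 3), and 22 of 25 flavonoid and anthocyanin genes rose. The photoprotection gene ELIP1 went from 11.1 ± 2.02 to 650 ± 35.4 CPM. Auxin response genes were lower in 21 of 24 cases, and ACS5 fell from 45.1 ± 3.91 to 0.425 ± 0.0677 CPM.

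Of the flavonoid and anthocyanin genes in spaQ, 22 were higher, 2 lower and 1 not called (median 4.55, adjusted p = 1.06e-06, and adjusted p = 0.0772 with an estimated correlation). The late anthocyanin genes LDOX (8.68) and DFR (7.86), the transport gene TT19 (7.97) and the regulator TT8 (6.04) averaged at most 0.117 CPM in Col-0. Without Col-0 replicate 1 the values of LDOX and TT8 were 8.06 and 7.93. The flavonol regulator MYB12 rose by 5.97, FLS1 by 5.08, CHI by 4.55 and UGT78D2 by 4.17, and the 2 that fell were PAL1 (-0.55) and EGL3 (-0.50), the latter not called without spaQ replicate 1 (-0.44) or 3 (-0.40). Photoprotection and UV response had 7 genes higher and 1 not called (median 4.41, adjusted p = 0.000122, and adjusted p = 0.2 with an estimated correlation), with ELIP2 at 6.07, ELIP1 at 5.86 and RUP2 at 5.25. Light-signalling regulators had 14 genes higher and 7 lower (median 0.34, or -0.03 with library totals, adjusted p = 0.115). BBX25 rose by 7.04, HYH by 4.53, GLK2 by 2.23 and HY5 by 1.17 (SE 0.09), and FHL and FHY1 fell by 3.04 and 1.72. Of the PIF factors and their targets 12 fell and 4 rose (median -1.16, adjusted p = 0.0209, 0.0933 with library totals, and adjusted p = 0.2 with an estimated correlation), with PIF3 at -1.52, PIL1 at -0.78, PIF5 at 2.55 and PIF7 at 4.66, and PIF4 was not called (0.10). Clock genes were higher in 12 cases and lower in 3 (median 2.5, adjusted p = 0.000886, and adjusted p = 0.208 with an estimated correlation), with PRR9 at 5.16, LNK2 at 3.34, PRR5 at 3.21 and CCA1 at 2.74.

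Plastid and carbon lists rose in spaQ. Antenna genes were higher in 16 cases and not called in 1, LHCB1.4 (median 2.43, adjusted p = 5.42e-08, and adjusted p = 0.234 with an estimated correlation), with LHCB1.1 at 5.80 and LHCA1 at 3.66. All 22 photosystem genes rose (median 2.73, adjusted p = 7.51e-11, and adjusted p = 0.209 with an estimated correlation), including PSBO2 (4.59) and PSBS (3.35), which acts in thermal dissipation. Of the Calvin cycle genes 16 rose and RBCS2B fell (median 3.44, adjusted p = 1.28e-08, and adjusted p = 0.209 with an estimated correlation), with FBA1 at 4.99, RCA at 4.90 and GAPA2 at 4.61. Chlorophyll biosynthesis had 21 genes higher and 2 lower (median 2.00, adjusted p = 2.55e-07, and adjusted p = 0.209 with an estimated correlation). CHLH rose by 3.18 and DVR, a divinyl reductase gene, by 2.9, and PORA and PORB fell by 6.52 and 4.05. All 12 carotenoid genes rose (median 2.13, adjusted p = 8.16e-07, and adjusted p = 0.208 with an estimated correlation), with ZEP at 3.90, BCH2 at 3.59 and the phytoene synthase gene PSY at 2.12. Nitrogen assimilation and photorespiration had 11 genes higher and 1 lower (median 3.09, adjusted p = 3.78e-05, and adjusted p = 0.209 with an estimated correlation), with HPR1 at 4.67, AGT1 at 4.21 and NRT1.1 at -2.38. Starch genes were higher in 11 cases and not called in 1 (median 1.84, adjusted p = 0.000122, and adjusted p = 0.285 with an estimated correlation), with BAM3 at 6.15 and the starch synthase gene GBSS1 at 3.37.

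Growth hormone lists fell in spaQ. Auxin response had 21 genes lower, 1 higher and 2 not called (median -2.66, adjusted p = 2.55e-07, and adjusted p = 0.208 with an estimated correlation), with IAA6 at -8.94, IAA19 at -5.59 and IAA29 at -5.51. Without spaQ replicate 1 IAA6 stood at -10.20, and without spaQ replicate 2 IAA6 and IAA29 stood at -8.25 and -6.12. Of 12 brassinosteroid genes 11 fell and 0 rose (median -0.83, adjusted p = 0.000633, and adjusted p = 0.2 with an estimated correlation), with BR6OX1 at -3.80 and DWF4 at -1.62. Ethylene genes were lower in 9 cases and higher in 1 (median -1.23, adjusted p = 0.0028, and adjusted p = 0.2 with an estimated correlation), with ACS5 at -6.69 and HLS1 at -3.21. Gibberellin genes were lower in 11 cases and higher in 4 (median -0.57, adjusted p = 0.0331, 0.0919 with library totals, and adjusted p = 0.2 with an estimated correlation), with GA20OX1 at -5.26 and RGL1 at -2.35. Expansin and xyloglucan enzyme genes were lower in 15 cases and higher in 7 (median -1.61, adjusted p = 0.00824, 0.0923 with library totals, and adjusted p = 0.480 with an estimated correlation), with XTH17 at -5.76, XTH30 at -3.19, EXPA8 at -3.12 and XTH22 at 2.61.

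Stomatal lineage and guard cell markers were higher in 13 of 14 cases in spaQ (median 1.52, adjusted p = 0.000808, and adjusted p = 0.2 with an estimated correlation), with BASL at 2.52, FAMA, which specifies guard cells, at 2.14 and KAT1 at -1.17. Seed storage and late embryogenesis had 11 genes lower, 1 higher and 6 not called (median -1.27, adjusted p = 0.00824, 0.0919 with library totals, and adjusted p = 0.480 with an estimated correlation). CRU2 fell by 3.87 and ABI3, a regulator of seed maturation, by 2.40, and CRU1 (-0.38) and CRU3 (-0.68) were not called. Without spaQ replicate 1 the values were -4.49 for CRU2 and -0.84 and -1.2 for CRU1 and CRU3, both then called, as they also were with library totals (-0.75 and -1.05). CRU3 was further called with limma-voom (-0.86), with no filter (-0.67), with only 2 genotypes in the fit (-0.67) and without cop1-4 replicate 1 (-0.68). Salicylate and pathogen defence had 6 genes lower and 1 higher (median -1.26, adjusted p = 0.0331, and adjusted p = 0.266 with an estimated correlation), PR1 at -8.07 among them, a call lost with library totals (0.0989) and with no filter (0.0669). Cuticular wax had 5 genes lower and 2 higher (median -1.87, also with WSD1 at its bound, adjusted p = 0.0640, or 0.0499 with no filter). CER1 fell by 3.54, and WSD1 was at 0 in all spaQ libraries and so at least 61.5-fold lower. The targeted loci had an adjusted p of 0.0745, which passed the threshold with no filter (0.0486) and without Col-0 replicate 2 (0.0486) or cop1-4 replicate 1 (0.0488). The lists not called were jasmonate (2 higher, 6 lower, median -0.83, adjusted p = 0.117), fatty acid breakdown and the glyoxylate cycle (7 higher, 3 lower, median 0.16, or -0.212 with library totals, adjusted p = 0.164), root markers (7 higher, 2 lower, median 0.58, adjusted p = 0.266), cell division (2 higher, 4 lower, median -0.22, adjusted p = 0.254), reference genes (4 higher, 2 lower, median 0.16, or -0.212 with library totals, adjusted p = 0.321) and glucosinolates (8 higher, 10 lower, adjusted p = 0.927). For glucosinolates the median was -0.36 and the mean 1.1, with camera's direction upward. Members of these lists included VSP1 (-6.39, or -5.72 and -7.32 without spaQ replicate 2 and 3), AOC2 (6.24), ICL (2.00), PMDH2 (3.58), CASP1 (-2.73), UGT74C1 (5.47) and MYB51 (-2.07), all called. Counts adjusted over the list alone were the same except for 2 higher auxin genes and 11 lower glucosinolate genes.

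The largest rises in spaQ under the rule for named genes were CYP706A6, at 16.7 ± 1.4 CPM (SD, n = 3) and at least 190-fold higher than in Col-0, AT3G09450 (10.58), AT2G15020 (10.38), AT1G65490 (10.31), AT3G28270 (10.25), THI2.2 (9.31), the serine carboxypeptidase-like gene scpl10 (9.25), NDA1 (9.12), AT1G66540 (9.00) and AT1G07450 (8.73). Genes near 0 in Col-0 had uncertain sizes: AT3G09450 stood at 13.05 without Col-0 replicate 3, scpl10 at 12.22 without Col-0 replicate 2 and 8.65 without replicate 1, and AT1G65490 and AT1G07450 at 11.07 and 9.48 without replicate 1. The largest falls under the same rule were AT1G49570 (-9.86), MRN1 (-9.55), ATPMEPCRD (-8.28), AIR1 (-7.74), which is overlapped over most of its length, AT5G44440 (-7.29), the tonoplast aquaporin gene TIP2;3 (-7.00), the nitrate transporter gene NRT1.5 (-6.90), the sugar transporter gene SWEET3 (-6.74), ACS5 and PORA.

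Between spaQ and Col-0, edgeR's quasi-likelihood test called 14878 of 20779 genes (71.6%), 7386 higher and 7492 lower, and 6977 changed at least 2-fold (3503 higher, 3474 lower). Libraries did not overlap for 75.4% of genes, where chance gives 10%. With library totals 29.9% of 15931 called genes were higher, against 49.6% with TMM. Of the 28 lists 19 were called, 11 upward and 8 downward, and none with an estimated correlation (lowest adjusted p = 0.0772).

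Set directly against cop1-4, spaQ seedlings had far higher flavonoid transcripts and lower antenna transcripts. CHS stood at 50.9 ± 1.39 CPM in cop1-4 and 613 ± 87.4 CPM in spaQ (SD, n = 3), and FLS1 at 10.1 ± 0.843 and 101 ± 11.3 CPM. LHCA1 went the other way, from 2018 ± 106 to 877 ± 117 CPM, as did the aquaporin gene TIP2;3, from 73.6 ± 5.78 to 2.75 ± 0.475 CPM.

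Of 25 flavonoid and anthocyanin genes 22 were higher in spaQ than in cop1-4, 0 lower and 3 not called (median 2.82, adjusted p = 1.69e-12). It was the 1 list still called with an estimated correlation (adjusted p = 0.0108). UGT79B1 was higher by 5.68, LDOX by 5.64, DFR by 5.16 (6.06 without cop1-4 replicate 3), TT19 by 4.86, CHS by 3.59, FLS1 by 3.32 and MYB12 by 2.73. PAP1, a MYB activator of anthocyanin genes, and MYB111 were lower in cop1-4 than in Col-0 (-1.37 and -1.99) and higher in spaQ (1.93 and 1.22), with differences of 3.3 and 3.22. The fall of PAP1 in cop1-4 was not called without cop1-4 replicate 2 (-1.2). HY5 also went in opposite directions, with a difference of 1.54 (SE 0.09). Photoprotection and UV response had 6 genes higher and 1 lower (median 1.29, adjusted p = 0.004, and adjusted p = 0.560 with an estimated correlation), with ELIP1 at 3.54, ELIP2 at 3.16 and RUP2 at 1.35.

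**Figure D3:**
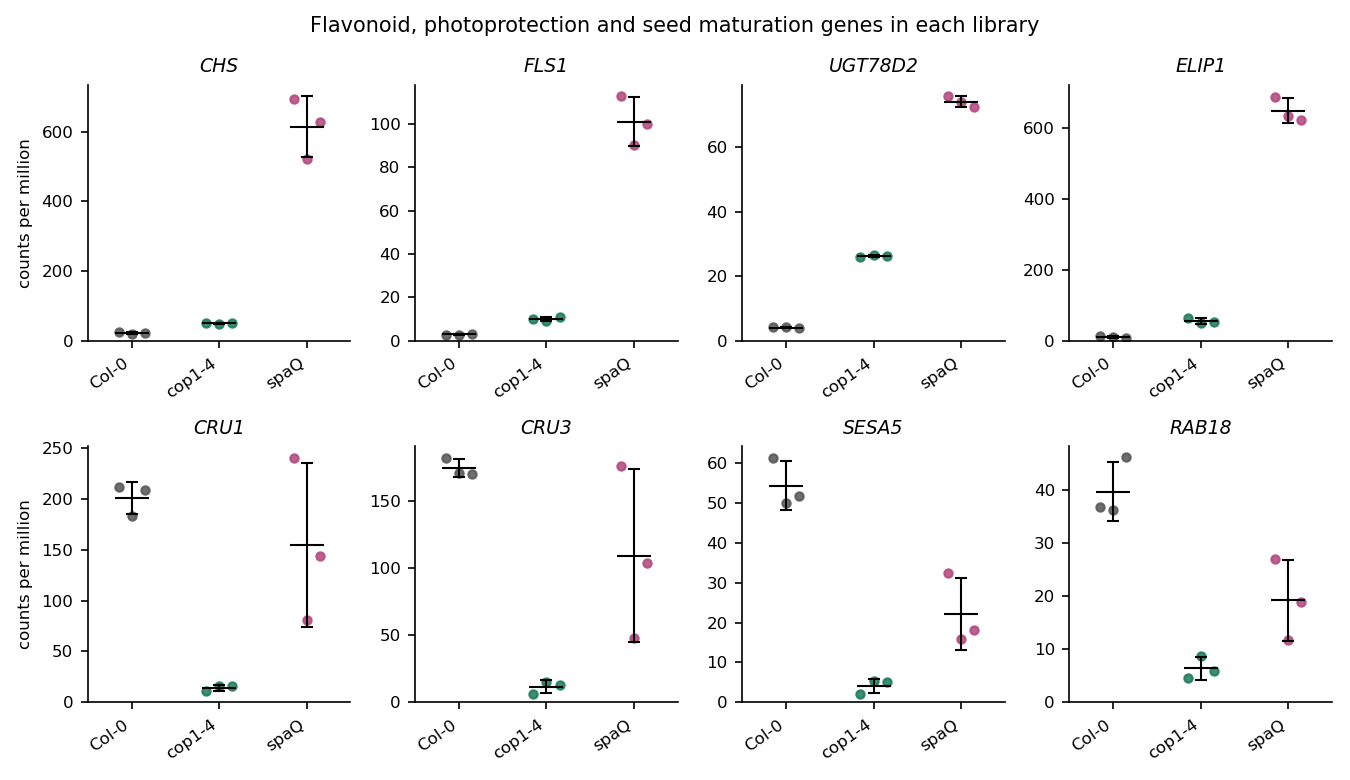
CPM (y axis, linear from 0) of CHS, FLS1, UGT78D2, ELIP1, CRU1, CRU3, SESA5 and RAB18 in each library (points) of Col-0, cop1-4 and spaQ, with the mean and SD of 3 libraries as bars. CHS averaged 613 CPM in spaQ against 50.9 in cop1-4, and the spaQ libraries of CRU1 were spread around 155 with an SD of 80.5.

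Among plastid lists, 16 of 17 antenna genes were lower in spaQ than in cop1-4 (median -0.97, adjusted p = 1.69e-07, and adjusted p = 0.680 with an estimated correlation). LHCB1.4 differed most (-5.87), with 6.95 ± 2.17 CPM in Col-0, 483 ± 82.6 in cop1-4 and 8.27 ± 1.67 in spaQ (SD, n = 3). Its reads can be shared with other LHCB1 genes, so the value is uncertain. LHCB4.3 was the 1 antenna gene that was higher (1.12). Calvin cycle genes were higher in 11 cases and lower in 0 (median 0.37, adjusted p = 0.00112, and adjusted p = 0.761 with an estimated correlation), with FBA1 at 1.03 and SBPASE at 0.66. Chlorophyll biosynthesis had 14 genes higher and 2 lower (median 0.53, adjusted p = 0.000869, and adjusted p = 0.761 with an estimated correlation), with DVR at 1.27 and PORA at -1.21. Carotenoid genes were higher in 10 cases and lower in 0 (median 0.52, adjusted p = 7.45e-05, and adjusted p = 0.680 with an estimated correlation), with BCH2 at 1.08 and PSY at 0.94. Photosystem subunits had 3 genes higher, 10 lower and 9 not called (median -0.19, adjusted p = 0.107), and PSBS was 1 of the higher ones (1.1).

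Auxin response had 12 genes lower and 5 higher in spaQ than in cop1-4 (median -0.58, adjusted p = 0.0257, and adjusted p = 0.842 with an estimated correlation), with IAA6 at -2.46, IAA29 at -1.88 and IAA19 at -1.18. IAA6 stood at -3.73 without spaQ replicate 1, and IAA6 and IAA29 at -1.78 and -2.48 without spaQ replicate 2. The call was lost without cop1-4 replicate 2 (median -0.34, adjusted p = 0.0565). Brassinosteroid genes were lower in 9 cases and higher in 1 (median -0.36, adjusted p = 0.00668, and adjusted p = 0.421 with an estimated correlation), with BR6OX1 at -1.78 and DWF4 at -0.76. Seed storage and late embryogenesis had 9 genes higher, 2 lower and 7 not called (median 1.09, adjusted p = 0.0494, and adjusted p = 0.929 with an estimated correlation). EM6, a late embryogenesis gene, was higher by 5.38 (4.70 and 6.73 without cop1-4 replicate 1 and 3), CRU1 by 3.44, CRU3 by 3.24 and SESA5 by 2.45, whereas ABI3 was lower by 1.35 (log2 fold change -1.35) and CRU2 did not differ detectably (0.02, SE 0.34). The list call was lost with RLE size factors (0.0596) and without Col-0 replicate 1 (0.071), 2 (0.0753) or 3 (0.0553), cop1-4 replicate 1 (0.0996, median 0.79), spaQ replicate 1 (0.176, median 0.89) or spaQ replicate 3 (0.0548).

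The other lists were not called between spaQ and cop1-4. Median log2 fold changes lay between -0.24 and 0.24 for targeted loci (2 higher, 2 lower, -0.24, adjusted p = 0.729), gibberellins (7 higher, 2 lower, 0.08, 0.298), ethylene (3 higher, 1 lower, -0.12, 0.729), expansins and xyloglucan enzymes (4 higher, 9 lower, -0.10, 0.471), the clock (4 higher, 7 lower, -0.04, 0.729), glucosinolates (4 higher, 6 lower, 0.03, 0.927), starch (4 higher, 4 lower, 0.04, 0.729), stomatal markers (4 higher, 1 lower, 0.11, 0.641), cell division (4 higher, 2 lower, 0.07, 0.542), reference genes (3 higher, 2 lower, 0.12, 0.729) and fatty acid breakdown and the glyoxylate cycle (9 higher, 1 lower, 0.23, 0.0655). Medians near 0 turned sign for starch with no filter (-0.078), with library totals (-0.016) and without cop1-4 replicate 2 (-0.003) or 3 (-0.035), and for glucosinolates with library totals (-0.029) and without cop1-4 replicate 1 (-0.068). The list of fatty acid breakdown was called with no filter (0.0437) and without spaQ replicate 2 (0.0162). Nitrogen assimilation and photorespiration had a median of 0.28 (6 higher, 2 lower, adjusted p = 0.496), and salicylate and pathogen defence a median of -0.70 (1 higher, 5 lower, adjusted p = 0.0655), the latter called without spaQ replicate 2 (0.0125). Median and mean had opposite signs for light-signalling regulators (8 higher, 7 lower, -0.06 and 0.18, adjusted p = 0.729), PIF factors and targets (5 higher, 6 lower, 0.07 and -0.05, 0.914), jasmonate (2 higher, 2 lower, 0.07 and -0.21, 0.927) and root markers (2 higher, 3 lower, -0.18 and 0.17, 0.820). The medians of PIF factors and targets without spaQ replicate 2 and of jasmonate without spaQ replicate 1 were -0.001 and -0.005. Cuticular wax had 2 genes higher and 3 lower (adjusted p = 0.927), with WSD1, which was at 0 in all libraries of both mutants and so has no measured difference, counted as unchanged. Within these lists PIF4 was lower in spaQ than in cop1-4 (-1.50), PIL1 higher (1.49), PRR5 and PRR7 lower (-1.26 and -1.23), LHY, a clock gene, higher (0.89), BAM3 higher (1.45), PR1 lower (-4.84) and CASP1 lower (-1.2). Adjusted over the list alone, counts changed to 3 lower targeted loci, 11 lower photosystem genes, 15 higher and 3 lower chlorophyll genes, 6 higher PIF genes, 13 lower auxin genes, 5 higher expansin genes, 5 higher starch genes, 3 higher wax genes, 2 higher and 6 lower defence genes, 3 higher stomatal genes and 5 higher and 3 lower cell division genes.

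Apart from CHS, FLS1, ELIP1 and CRU1, the largest rises in spaQ over cop1-4 under the rule for named genes, which leaves out genes with low counts, were AT3G01345 (8.63), from 0.391 ± 0.165 to 150 ± 12.8 CPM (SD, n = 3), AT3G43850 (7.74, or 7.06 and 11.83 without cop1-4 replicate 1 and 3), AT1G68250 (7.50, or 8.24 without cop1-4 replicate 3), the cold- and abscisic acid-induced gene KIN1 (4.66), the starch-related orphan gene QQS (4.2) and AT3G17520 (3.62). Apart from LHCB1.4, the largest falls under that rule were TIP2;3 (-4.76), SWEET3 (-4.66), AT1G29100 (-4.47), NRT1.5 (-4.40), AT4G37700 (-4.37), the osmotin gene OSM34 (-4.21), PBS3, which acts in salicylate synthesis (-4.18, or -6.23 without spaQ replicate 2), the ATPase gene AATP1 (-4.12) and AT3G05945 (-3.92). TIP2;3, SWEET3, NRT1.5 and PBS3 had already fallen in cop1-4 against Col-0 by 2.25, 2.08, 2.5 and 2.1.

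The comparison of spaQ with cop1-4 gave 9862 called genes of 20779 (47.5%), 4980 higher and 4882 lower, of which 2054 differed at least 2-fold (839 higher, 1215 lower). Libraries did not overlap for 57.3% of genes, where chance gives 10%. Of the 28 lists 9 were called, 6 upward and 3 downward, and 1 with an estimated correlation.

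Most genes that changed in cop1-4 changed in the same direction in spaQ. Against Col-0, 5520 genes were higher in both mutants and 5363 lower in both, where independent lists would share 2350 and 2270. RCA, LHCA1, PIF5 and PRR9 were among the shared rises and PORA, IAA19, ACS5 and MRN1 among the shared falls. Both comparisons use the same Col-0 libraries, and splitting 3 controls would leave fewer than 2 in a part, so some of the excess may come from the shared controls. In 20 draws, all 9 libraries were simulated without change from the mean Col-0 levels, so the real Col-0 libraries did not enter. At most 5 genes of a draw were called in 1 mutant and 0 in both, which unchanged groups nearly ensure. That 0 does not measure what the real shared controls add to the overlap. Fold changes of the mutants had a Pearson correlation of 0.887 across genes, which are not independent replicates, against 0.477 in the simulated draws (0.465 to 0.492), and a covariance of 1.78 against 0.0168, a difference of 1.76. Of the 10883 genes called in both mutants in the same direction, 5637 differed between spaQ and cop1-4, and 4782 of these (84.8%) had gone further in spaQ, such as CHS, ELIP1, TIP2;3 and ACS5. The remaining 855, such as LHCA1, PRR7 and FKF1, had gone further in cop1-4. Another 1764 genes were called in cop1-4 alone and 3733 in spaQ alone, with the difference itself called for 1097 and 2470. Opposite directions were called for 262 genes with TMM scaling, such as HY5, PAP1, MYB111, QQS and AT3G01345.

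**Figure D4:**
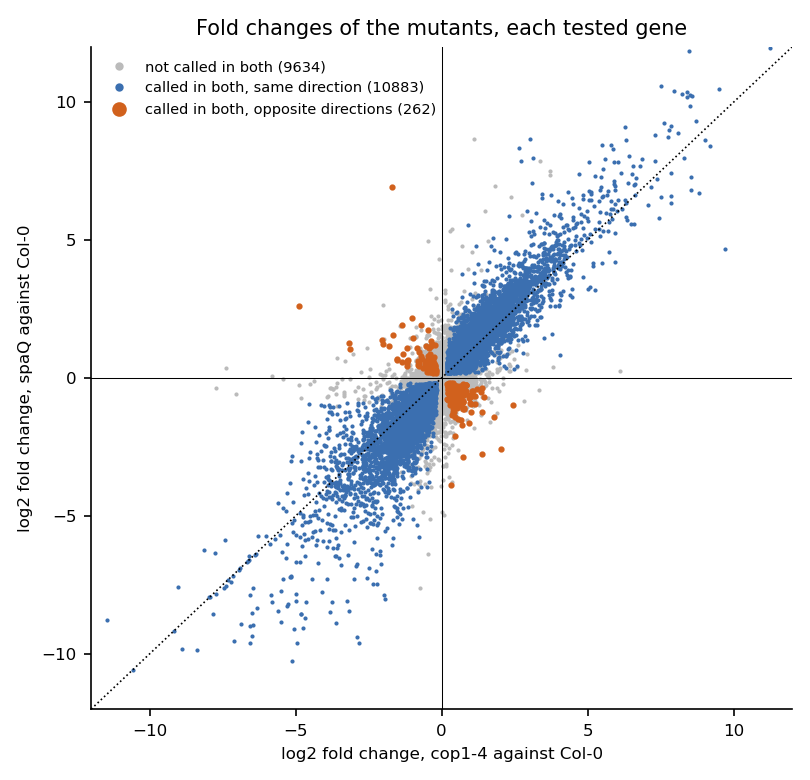
log2 fold change in spaQ against Col-0 (y axis) over that in cop1-4 against Col-0 (x axis), with a point for each tested gene, the diagonal dotted, blue for 10883 genes called in both mutants in the same direction, orange for 262 called in opposite directions and grey for the rest. Blue points fill the lower left and upper right, and most of those far from the diagonal lie on the side of larger changes in spaQ.

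Both of the authors' deposited tables held only genes with an absolute log2 fold change of at least 1 and an adjusted p-value below 0.05. Their like counts here are therefore the 5124 and 6977 genes called at 2-fold. The shares of each table given next count calls of any size. The authors' deposited table for cop1-4 listed 5249 regulated genes, 2665 higher and 2584 lower. Of the genes in the authors' deposited table for cop1-4, 4999 were tested here and 4997 (95.2% of the table) were called in the same direction. The authors' deposited table for spaQ listed 7261 genes, 3578 higher and 3683 lower, of which 6861 were tested here and 6860 (94.5%) were called in the same direction. No gene of either of the authors' deposited tables was called in the opposite direction here. Fold changes in the authors' deposited tables and in the fit here had correlations of 0.997 across genes for both mutants. Of the genes called at 2-fold here, 4933 of 5124 and 6853 of 6977 were in the authors' deposited tables.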

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

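The tests of the SPA transcripts, those of the flavonoid list against matched lists and under other scalings, and that of the spread of the seed genes were chosen only after the results were seen; those that left out 1 library and the splits of the libraries were chosen before.

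Genes that went in opposite directions in the mutants stood apart as differences between the genotypes. Against Col-0, 262 genes were called in opposite directions in cop1-4 and spaQ with TMM scaling, and for 15 of them both changes were at least 2-fold. The difference between the mutants was called for all 262, which called changes of opposite sign nearly ensure, so it adds no support. The count was not repeated with another scaling. Small rises, such as that of BPC4 in cop1-4 (0.18, with -0.199 in spaQ), are below the size of the median's shift with library totals (-0.31 in cop1-4 and -0.39 in spaQ). The difference between spaQ and cop1-4 was 8.635 for AT3G01345 and 7.496 for AT1G68250 (8.24 without cop1-4 replicate 3). For the orphan gene QQS the difference was 4.2, for PAP1 3.3, for MYB111 3.216 and for HY5 1.539. The osmotin gene OSM34 had a difference of -4.21, with 0.33 in cop1-4 and -3.88 in spaQ. Its rise in cop1-4 was not called with library totals (0.02) or without Col-0 replicate 2 (0.32), Col-0 replicate 3 (0.28), cop1-4 replicate 2 (0.35) or cop1-4 replicate 3 (0.22). The fall of PAP1 in cop1-4 was not called without cop1-4 replicate 2 (-1.2). CYP79B2, an enzyme gene of indole glucosinolates, had a difference of -1.04, from 0.25 in cop1-4 to -0.79 in spaQ. Its rise in cop1-4 turned to -0.06 with library totals and was not called with DESeq2 (0.23) or without Col-0 replicate 1 (0.24) or 2 (0.24) or cop1-4 replicate 2 (0.2) or 3 (0.22).

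No SPA locus was lower in the libraries labelled spaQ than in Col-0 with TMM scaling, although spaQ stands for a mutant in all of them, and with library totals, which moved the median of all genes to -0.39, SPA2 was called lower (-0.31). An exchange of the Col-0 and spaQ labels was predicted to give a ratio of 1 or more between counts of genes called at 2-fold. Libraries labelled spaQ and cop1-4 differed in 0.4009 times as many genes as those labelled cop1-4 and Col-0. The prediction holds only if cop1-4 lies nearer to spaQ than to the wild type. Were cop1-4 nearer to the wild type, an exchange would also give a ratio below 1. The ratio therefore cannot decide on this exchange. Alleles that remove part of the counted transcript may be part of the pattern, as a hypothesis from the same data: the mean difference of SPA1 to SPA4 between spaQ and cop1-4 was -0.868 and lay at percentile 0.78 of 10000 random sets of 4 genes with like changes in cop1-4 (median 0.205, central 95% -0.606 to 0.959). SPA1 (-2.15) and SPA3 (-1.83) carry that mean, whereas SPA2 was not called (-0.24) and SPA4 was called higher (0.75), against the explanation, so the value speaks for SPA1 and SPA3 alone. An exchange of the cop1-4 and spaQ labels cannot be told apart from the labelled design, since the lowest SPA change in the libraries labelled cop1-4 (0.304, for SPA2, or -0.013 with library totals) would argue against it only if the alleles lower the count, which the labels do not state.

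Flavonoid genes were higher in spaQ than in cop1-4, with a list median of 2.82. Larger changes of all genes in spaQ were argued against as the whole cause, since the median lay at percentile 100 of 10000 random lists matched on the change in spaQ against Col-0 (median 0.561, central 95% 0.273 to 0.911). A single library was argued against by a lowest median of 2.677 when each of the 6 libraries was left out. The lowest median over TMM, RLE and library totals was 2.771, which by itself decides nothing on scaling, because these moved the median of all genes only between -0.069 and 0.005. A scaling factor shifts all genes alike, however, and between spaQ and cop1-4 the reference genes had a median of 0.12 (-0.813 to 0.599) and the antenna genes -0.97. These values argue against scaling as the cause of the distance between the flavonoid genes and those lists. A difference between the mutants in the control of flavonoid genes stays open as a hypothesis, found and tested on the same data, and growth or batch differences that follow genotype were not tested. The name cop1-4 stands for a weak COP1 allele, and the design cannot tell allele strength from a difference between COP1 and SPA proteins.

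Seed storage and late embryogenesis genes were low in cop1-4 and less so in spaQ, with a list median of 1.09 between the mutants. Different shares of 1 seed source of fixed make-up were argued against, because the members' changes had a standard deviation of 2.29, 6.234 times their median standard error of 0.367. Leaving out spaQ replicate 1, the highest library for most members, left the median above 0 (0.889), so that library alone did not make the direction. The list was not called without it (adjusted p = 0.176 against 0.0494, and 0.00364 to 0.929 over all alternatives), and the median without cop1-4 replicate 1 was 0.79. Differences in seed batch or in the pace of germination stay open and were not tested.

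For comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05, and 1 of 10 splits, the real one, gave the largest count of genes in each. For cop1-4 against Col-0 edgeR on the 6 libraries gave 12394 called genes in the real split, 5040 at 2-fold and 22 lists, and the highest other split 0, 0 and 17. For spaQ against Col-0 the values were 14868, 6918 and 19 against 0, 0 and 17. For spaQ against cop1-4 they were 9960 and 1912 genes against 0 and 0, and 7 lists against 12, with 4 of 10 splits giving as many lists. Among 100 splits of the 9 libraries into 3 groups, the real one alone (1 of 100) gave as many genes called in both mutants in the same direction, 10883 against 2072 for the highest other. Groups that mix genotypes have a larger spread, which lowers the number of genes called, so such splits do not stand for unchanged groups. No other split reached the real count, but these splits do not exclude chance for it. The correlation of the mutants' changes was reached in 15 of 100 splits (0.887 against a highest other of 0.964), so these splits could not exclude chance for it. They decide little about the correlation, since groups of mixed genotypes also gave high values with 0 genes called in both (0.923, for example), and in the 20 simulated draws of unchanged groups it was 0.465 to 0.492.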

How the results depend on the processing

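The tests with library totals and without overlapping genes were chosen only after the results were seen. Counts of called genes stayed within 1.5 times under each alternative run: 10625 to 14307 for cop1-4 against Col-0, 12911 to 15931 for spaQ against Col-0 and 7259 to 10232 for spaQ against cop1-4. The lowest came at a threshold of 0.01 and the highest with library totals, except in spaQ against cop1-4, where it came without Col-0 replicate 2. Counts at 2-fold ranged over 4479 to 5616, 6095 to 7701 and 1779 to 2222, and genes called in both mutants in the same direction over 9057 to 12441. The share of the authors' deposited regulated genes called here (94.8%) ranged from 83% without 6065 overlapping genes to 99.7% with no filter. Thinning each library to the smallest total of 22482588 lowered the counts to 12579, 14510 and 9540 called genes. Leaving out organelle genes could not be run, because the count table holds none.

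Scaling by library totals turned the direction of several small changes: COP1 in cop1-4 from 0.008 to -0.308, SPA1, SPA2 and SPA3 in spaQ to -0.053, -0.31 and -0.007, SPA2, IAA14, CYP79B2 and CYP79B3 in cop1-4 to -0.013, -0.049, -0.059 and -0.266, and CPD in spaQ to -0.241. With that scaling COP1 in cop1-4, SPA2 in spaQ, CYP79B3 in cop1-4 and CPD in spaQ were called lower. That scaling shifts all genes by the amounts given with the library totals. The call of SPA2 in cop1-4 (0.304) was lost at a threshold of 0.01 (0.304, adjusted p = 0.0202), which follows from the stricter threshold, and without single libraries the value ranged from 0.164 to 0.39. The correlation of the mutants' changes (0.887) was 0.793 with no filter, 0.9 with the CPM filter, 0.895 with only 2 genotypes in each fit and 0.872 to 0.887 without single libraries. The cause was not tested. With an estimated correlation between genes, camera called 0, 0 and 1 lists in place of 21, 19 and 9, and fry, which tests each list on its own, called 27, 27 and 16. The lost camera calls do not rest on the correlation between genes alone. For gibberellins in cop1-4 the estimate was -0.012, below the preset 0.01, yet camera's adjusted p went from 0.000791 to 0.137.

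The replicate numbers did not pair the libraries: same-numbered libraries had deviations from their group means with correlations of -0.296 to 0.33 over 9 pairs, 1 above 0.1, and 0 libraries correlated best with their own number in both other genotypes. Differently numbered libraries of Col-0 and cop1-4 had values from -0.379 (Col-0 replicate 3 with cop1-4 replicate 1) to 0.474 (Col-0 replicate 2 with cop1-4 replicate 1). Structure shared across the numbers was not tested. With a replicate block 12727, 14731 and 9585 genes were called, and the block ended the call of the cell division list in cop1-4 (adjusted p = 0.0521, against 0.0011 to 0.317 over all alternatives for that list). It also ended the call of FAMA between spaQ and cop1-4 (adjusted p = 0.0704, and 0.0483 to 0.171 over the alternatives that changed it) and made a call of CYCD3;1 there. The block changed no other call of a list or named gene.

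Of 22 main values and counts, 13 were counted as unchanged under all alternatives run, as were 403 of 424 alternative values. Counts and the share of the authors' deposited genes were counted as unchanged within 1.5 times, so 10625 called genes in place of 12909 pass. The correlation was counted as unchanged within 0.0073, the SD of its values from single replicates. Only the targeted loci among the 22 were judged by direction and call. For named genes, 436 of 462 values by comparison were unchanged under all alternatives. Of 9210 alternative values 9116 were unchanged, 50 lost the call, 40 gained it and 4 turned direction with a call in either fit. For the lists, 15 of 84 results were unchanged under all alternatives, and of 1260 alternative values 1152 were unchanged, 70 lost the call, 38 gained it and 0 turned direction with a call in either fit. Values that were called under neither setting are counted as unchanged, and of these 5 for COP1 in cop1-4, 30 for other named genes by comparison and 16 list medians changed sign, 10 of the 16 with library totals.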

Other observations

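The tests of the neighbours of the targeted loci were chosen only after the results were seen, as were the members named here from the glucosinolate list.

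Members of the glucosinolate list went both ways, and no test of its aliphatic or indole branch was made. MYB28, a regulator of the aliphatic branch, stood at 1.06 ± 0.181 CPM in Col-0, 6.91 ± 1.35 in cop1-4 and 11.9 ± 0.812 in spaQ (SD, n = 3), log2 fold changes of 2.68 and 3.46. MAM3, which elongates the side chain, rose by 3.56 and 3.73, and IPMDH1, of the same elongation steps, by 2.23 and 3.35. Of indole branch genes CYP83B1 went from 87.5 ± 9.26 to 53.1 ± 4.93 and 35.8 ± 3.63 CPM (-0.72 and -1.29), the regulator MYB51 fell in both mutants, and CYP79B3 had values of 0.05 (not called, or -0.27 and called with library totals) and -0.59. CYP79B2 went the other way in cop1-4 (0.25, a call not kept in several alternatives given above) and fell in spaQ (-0.79). The list as a whole was not called by camera in either mutant, whereas fry called it upward in both.

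Around each of the 5 targeted loci the 100 nearest tested genes were examined for called differences of at least 4-fold between spaQ and cop1-4 in genes that had changed more in spaQ than in cop1-4 against Col-0. SPA2 had 7 such neighbours, where the mean over all windows of that size was 1.71 and SPA2 lay at percentile 98.8. The loci were 5, so a high percentile for 1 of them carries less weight than for a locus looked at alone. SPA4 had 2, SPA1 and SPA3 had 1 each and COP1 had 0. In the opposite column, genes that had changed more in cop1-4, SPA4 had 3 neighbours and lay at percentile 97.1, SPA3 had 1 and the other loci had 0. OSM34 was 1 of the 7 neighbours of SPA2.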
